A study of Mus musculus with 22 samples.

How the data were processed

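RNA was sequenced from 8 mouse embryos at embryonic day 3.5 and from 7 cell lines with 2 technical replicate libraries each, 22 libraries in all. Per the labels, the technical replicates of a line come from different passages. Per the labels, the embryo libraries were made from amplified cDNA with another kit than the line libraries, so embryos and lines were never compared directly. The deposited table gives counts per gene symbol for all 22 libraries, raw and not normalized, as whole numbers for 21881 symbols, of which 2722 were 0 in every library. Per the submitters' processing notes, TopHat 1.3.1 and edgeR (no version) were the tools and mm9 was the genome build. The counting program, the annotation and the use of strand are not given in the sources used here. A second deposited table lists the authors' Nanog-regulated genes, with a direction word (UP or DOWN) for each and loci in mm9. Its unit is of the kind other: per the file headers the direction column deposited by the authors is a word and not a number. The 22 value columns of that table carry no stated unit and were not used, and the rule by which its genes were chosen is not stated. Loci are printed as given in the authors' deposited table, with no other build.

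Samples were grouped by the genotype, lineage, line and sex in their labels. The embryos were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust shrinkage, TMM scaling, filterByExpr) with 3 genotype groups and sex as terms. That fit gave null against the equally weighted mean of wild type and heterozygous (Nanog-bearing), null against wild type, null against heterozygous, heterozygous against wild type, and female against male. A second fit of null status by sex tested the interaction. For the lines, the counts of the technical replicates were summed, because replicates of a line are not independent, and the 7 lines were fitted without further terms for ES against TS, ES against XEN and TS against XEN. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The filter kept 12965 genes in embryos and 14687 in lines. The biological coefficient of variation was 0.979 in embryos and 0.346 in lines. A prior count of 2 was used for log2 CPM values only, and the fitted log2 fold changes kept the default of edgeR. The SE is the absolute log2 fold change divided by the square root of the F statistic of its test.

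Gene lists, comparisons, the rule for named genes and the first set of alternatives were fixed before the data were examined. The 22 lists were written from general knowledge. They covered epiblast and naive pluripotency, primitive endoderm, trophectoderm, formative and primed epiblast, the FGF and MAPK, Wnt, BMP with Nodal and TGF-beta, LIF and STAT3, Hippo and Notch pathways, p53 targets and apoptosis, cell cycle, glycolysis, chromatin regulators, 2-cell stage genes, oocyte and maternal transcripts, fibroblast and mesenchymal cells, blood cells, cumulus and oviduct cells, and immediate early and stress genes. Y-linked and X-inactivation genes were used only to check the sex labels. Nanog is in no list. Lists with at least 5 measured genes, 19 of 20, were tested with limma 3.58.1 camera at a preset correlation of 0.01 and adjusted over the lists. At the preset correlation this test counts genes and not embryos as replicates. The test was repeated with an estimated correlation and with fry. Lineage signatures were the 200 genes with the smallest p-values among those called and at least 2 log2 units above both other lineages, and were tested the same way. Nanog and its pseudogene Nanogpd are in the ES signature and were not taken out. Medians of lists and signatures were also set against 10000 random sets of tested genes matched on mean expression. For the authors' list, genes with the listed direction and genes called were counted.

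By the rule, named always were Nanog, Pou5f1, Sox2, Gata6, Gata4 and Cdx2. Named for a main comparison were the called genes with the largest changes, up to 8 each way in embryos and 5 each way in lines, whose values did not overlap between the groups and whose mean was at least 3 log2 CPM, leaving out predicted genes and pseudogenes. From each list up to 4 called members were taken by smallest p, or up to 2 members as values where fewer than 2 passed. For the other embryo comparisons up to 5 genes were taken by smallest adjusted p. For the lines, the text was narrowed after the values were seen to members of the lineage lists and, of each signalling list, the first 2 by p with more than 3 counts in both lineages, while the rest were tabulated only. Nanogpd, and list members that passed only when adjusted over the list alone, were named after their values were seen, as were members given beside them as not passing.

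Single values between groups of embryos were compared with two-sided exact permutation tests over all 70 splits. Depth per library is given with the results. Counting intervals are 95% exact intervals of the ratio of 2 counts, and a group at 0 counts was set to a limit of 3 counts over the group. Reads carried no molecular identifiers, so intervals and limits cover counting error only. A gene was counted as lost in an embryo at 3 counts or fewer when the other 7 embryos averaged at least 5 CPM, and this was repeated after thinning all embryo libraries to 14.8 M counts (M, mega).

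The pipeline was tested on simulated data of the same designs, drawn from a negative binomial with the common dispersion of the real data, with 200 changed genes. In the leading embryo comparison it called 1 of 12524 unchanged genes. For ES against TS cells it recovered 47 of 67 genes changed 4-fold, 66 of 67 changed 16-fold and 64 of 66 changed 64-fold, and for TS against XEN cells 47, 66 and 63. For female against male embryos it recovered 0, 8 and 46. A list of 30 genes shifted 4-fold was called and 0 of 19 unchanged lists were.

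Alternatives tried were DESeq2 size factors or upper quartile scaling in edgeR, no filter and a stricter filter on low counts (5 CPM in at least 4 embryos), the DESeq2 1.42.0 Wald test, limma voom with quality weights, no robust shrinkage, no sex term, a single control class, and leaving out each embryo or line in turn. For the lines they also included sex as a covariate, each technical replicate alone, and all 14 libraries with duplicateCorrelation or with the replicate number as a block. Whether replicate numbers pair libraries was checked on the 21 pairs of lines. The correlation of their replicate differences had a median of 0.01 and 2 of the 21 exceeded 0.1, so the numbers were not read as pairs. Signatures of 100 and 500 genes were tried as well. Some alternatives were added after seeing the data: leaving out null embryos F1 and M2, and restricting lists and signatures to genes with a mean of at least 32 CPM. All 22 libraries were kept, and genes were left out by the filter on low counts and from naming as stated.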

Results

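RNA was sequenced from 8 mouse embryos at embryonic day 3.5, the blastocyst stage, and from 7 cell lines that stand for the first lineages of the embryo. The embryos comprised 2 wild-type, 2 heterozygous and 4 Nanog-null embryos, with as many labelled female as male in each genotype. Nanog encodes a homeodomain transcription factor of the pluripotent epiblast. The lines were 2 embryonic stem (ES) lines, which model the epiblast, 3 trophoblast stem (TS) lines, which model the trophectoderm, and 2 extraembryonic endoderm (XEN) lines, which model the primitive endoderm. Each line had 2 technical replicate libraries, which gave 14 line libraries and 22 libraries in all. The titles of the ES libraries say serum free, and those of the TS and XEN libraries name no medium. Total counts, in mega-counts (M), were 27.9 ± 6.08 M in wild-type embryos (SD, n = 2), 19.0 ± 6.01 M in heterozygous embryos (n = 2) and 19.4 ± 2.28 M in Nanog-null embryos (n = 4). The single embryo libraries ranged from 14.8 to 32.2 M counts. The line libraries held 9.08 ± 0.604 M counts in ES cells (n = 4), 12.9 ± 2.83 M in TS cells (n = 6) and 17.5 ± 5.10 M in XEN cells (n = 4), with a range from 8.20 to 23.7 M.

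The targeted gene was examined first in every sample. Nanog counts were 3238 in the wild-type female embryo, 3456 in the wild-type male, 2038 in the heterozygous female and 791 in the heterozygous male. The Nanog-null embryos held 8 counts in F1, 7 in F2, 12 in M1 and 6 in M2. In CPM (counts scaled to M of the library total), Nanog was 122 ± 21.1 in wild-type embryos (SD, n = 2), 70.6 ± 24.0 in heterozygous embryos (n = 2) and 0.433 ± 0.153 in null embryos (n = 4). Nanog was 642 ± 65.4 CPM in the ES libraries (n = 4), 1.40 ± 0.902 CPM in the TS libraries (n = 6) and 0.242 ± 0.0735 CPM in the XEN libraries (n = 4). The authors' deposited table places Nanog on chromosome 6 from 122657585 to 122663796 in the mm9 build.

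The leading comparison asked which transcripts differed between the 4 Nanog-null and the 4 Nanog-bearing embryos, the latter being the equally weighted mean of wild-type and heterozygous. Nanog fell 196-fold, with a log2 fold change of -7.61 (SE 0.51, adjusted p = 0.000501, lower in 4 of 4 null embryos). Nanogpd, a pseudogene of Nanog that can share its reads, fell with it (log2 fold change -9.05, SE 1.07, adjusted p = 0.0477), and it is named here because so few genes were called. Pou5f1, which encodes the pluripotency factor OCT4, was 439 ± 75.6 CPM in null embryos (n = 4), 406 ± 21.8 CPM in wild-type embryos (n = 2) and 505 ± 79.3 CPM in heterozygous embryos (n = 2). Gata6, which encodes an early primitive endoderm factor, was 166 ± 39.4, 118 ± 4.64 and 176 ± 30.2 CPM in the same order, and Cdx2, which encodes a trophectoderm factor, was 55.9 ± 17.6, 63.7 ± 6.34 and 75.2 ± 26.4 CPM. Sox2 was 10.7 ± 12.0, 14.7 ± 7.04 and 6.0 ± 3.1 CPM. The fitted log2 fold changes were 0.06 for Pou5f1 (SE 0.21), 0.34 for Gata6 (SE 0.29), -0.22 for Cdx2 (SE 0.34), -1.62 for Sox2 (SE 1.79) and -3.88 for Gata4 (SE 2.04), none of them past the test. The direction for Sox2 was not settled, as it was 0.34 with no sex term, and with 1 embryo left out Pou5f1 (-0.034 to 0.14) and Cdx2 (-0.42 to 0.0064) changed sign too.

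**Figure D1:**
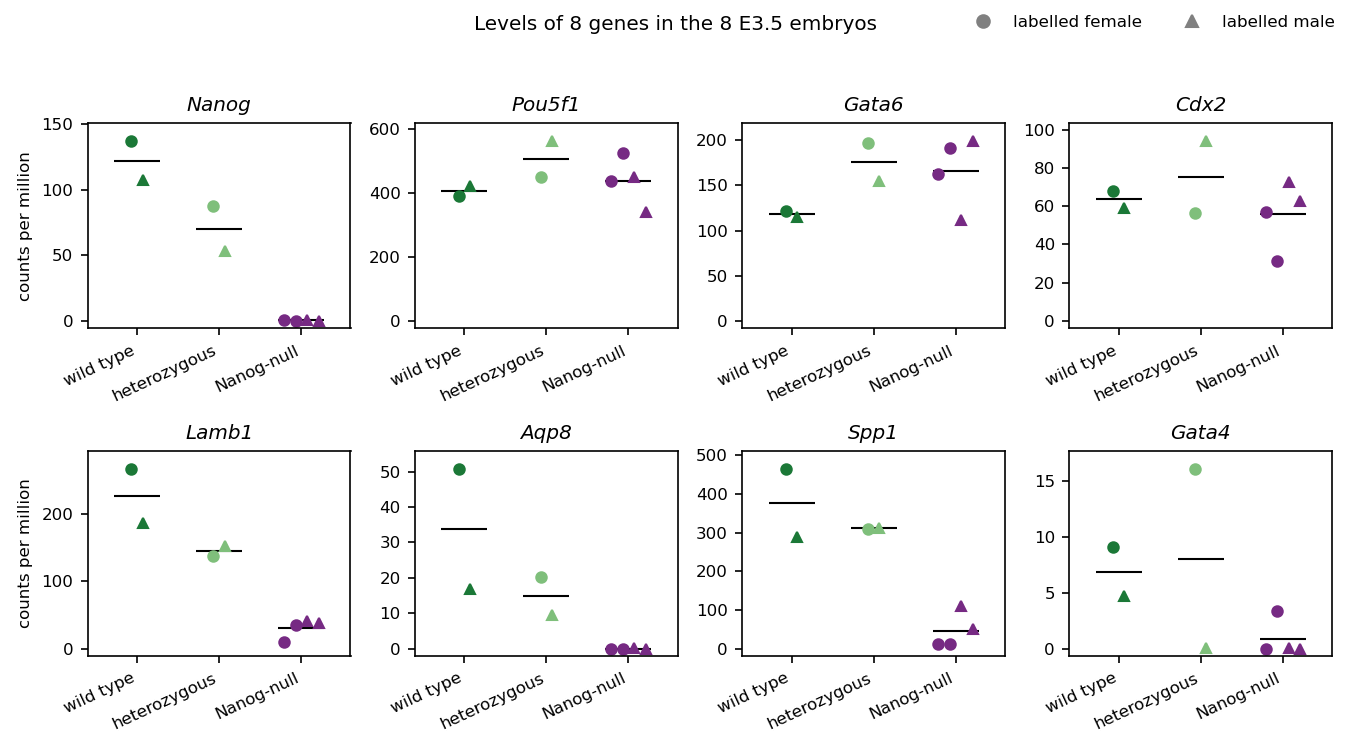
CPM (vertical axes) of 8 genes in each of the 8 embryos, by genotype (horizontal axes). Each point is 1 embryo and each bar is the mean of its group. Nanog lies between 0.300 and 0.624 CPM in the null embryos, and Lamb1 lies between 10.5 and 41.9 CPM there against 137 to 266 CPM in the Nanog-bearing embryos.

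In this comparison edgeR called 2 of 12965 tested genes, both lower in null embryos, while 644 genes had an unadjusted p under 0.05 (328 higher and 316 lower). DESeq2 called 87 genes (31 higher and 56 lower), among them Spp1, Aqp8 and Lamb1, and limma voom with quality weights called 0, with 1085 genes at an unadjusted p under 0.05 and Nanog itself at adjusted p = 0.190. The call of Nanogpd was lost when null embryo F1, F2 or M2 or either wild-type embryo was left out, which left 1 called gene each time. In simulated data of this design, edgeR recovered 0 of 67 genes changed 4-fold, 17 of 67 changed 16-fold and 52 of 66 changed 64-fold. A few-fold change was thus mostly not detectable in a gene with the common spread, which every simulated gene was given. The simulation does not speak for genes with a smaller spread.

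Primitive endoderm genes fell as a group in Nanog-null embryos (limma camera adjusted p = 3.44e-05 over 19 lists, median log2 fold change -2.46, 20 of 25 measured genes lower). The summed level of the list fell less, at 2345 ± 506 CPM in null embryos (SD, n = 4, 1879 to 2802). It was 2727 ± 257 CPM in heterozygous (n = 2, 2546 to 2909) and 3289 ± 491 CPM in wild-type embryos (n = 2), so null and heterozygous embryos overlapped. With an estimated correlation, which at -0.005 lay below the preset 0.01, camera gave the list an adjusted p of 0.114. The preset test counts genes and not the 8 embryos as replicates, so its p does not measure the spread between embryos. With fry the adjusted p was 0.00286 for a decrease. Among genes with a mean of at least 32 CPM, a limit chosen after seeing the data, preset camera gave the list an adjusted p of 0.00542 over 13 genes. None of its genes passed over all genes tested, and 8 passed when adjusted over the list alone, 7 lower and 1 higher. Laminin subunits of the basement membrane were among the lower ones: Lamb1 was 31.4 ± 14.2 CPM in null embryos (n = 4) against 227 ± 55.9 in wild-type (n = 2) and 145 ± 10.4 in heterozygous embryos (n = 2). Its log2 fold change was -2.46 (SE 0.43), that of Lama1 -4.50 (SE 1.47) and that of Lamc1 -1.45 (SE 0.45). Serpinh1, a collagen chaperone, fell by 3.32 on the log2 scale (SE 1.08), and Sparc, a secreted matrix protein gene, fell by 2.18 (SE 0.63). Aqp8, a water channel gene, had 0, 0, 2 and 0 counts in the null embryos against 142 to 1197 in the Nanog-bearing embryos, a ratio of 970 with a 95% counting interval from 268 to 8011. Srgn, which encodes a proteoglycan core protein, had 0 counts in all 4 null embryos and 305 in the 4 Nanog-bearing embryos together, at least 83.9-fold lower by the limit of 3 counts over the group. Cited1, a transcriptional co-regulator gene, rose by 2.25 (SE 0.48).

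Other primitive endoderm genes did not pass: the values were -3.43 for Sox17 (SE 2.70), -1.43 for Pdgfra (SE 0.63), -1.13 for Col4a1 (SE 0.49), -2.62 for Col4a2 (SE 1.08), -0.06 for Dab2 (SE 0.21) and 0.29 for Lrp2 (SE 0.35). The null libraries also lacked more genes that the other embryos expressed: 570, 300, 133 and 809 genes in F1, F2, M1 and M2 were at 3 counts or fewer although the other 7 embryos averaged at least 5 CPM, against 40 to 68 in the Nanog-bearing embryos. The means were 453 ± 298 (SD, n = 4) and 48.5 ± 13.2 (n = 4), two-sided exact permutation p = 0.0286, the smallest that the 70 splits allow. The number of genes detected at all overlapped, at 12537 ± 1071 in null and 13253 ± 416 in Nanog-bearing embryos (n = 4 each, exact permutation p = 0.314). After thinning to equal totals the exact permutation p was 0.143. Without null embryos F1 and M2, an alternative chosen after seeing the data, the primitive endoderm list had an adjusted p of 1.99e-05. Total counts overlapped between the groups, at 19.4 ± 2.28 M in null (n = 4) and 23.5 ± 7.13 M in Nanog-bearing embryos (n = 4), exact permutation p = 0.343.

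**Figure D2:**
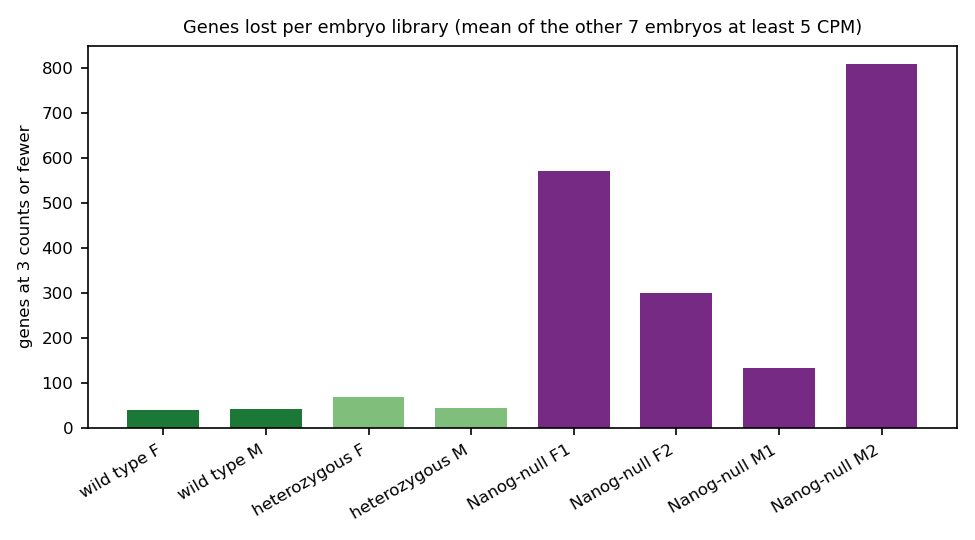
Number of genes at 3 counts or fewer (vertical axis) in each embryo library (horizontal axis), among genes whose mean in the other 7 embryos was at least 5 CPM. Each bar is 1 library, and the null libraries hold 133 to 809 such genes against 40 to 68 in the Nanog-bearing libraries.

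**Figure D3:**
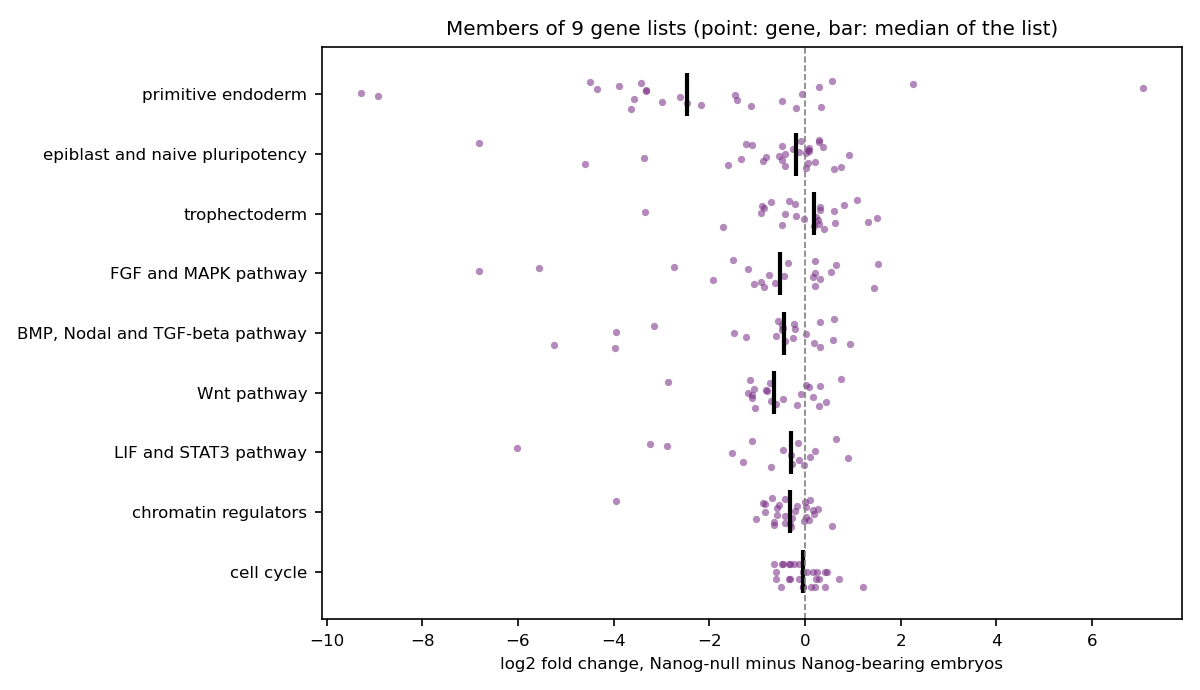
Log2 fold change between Nanog-null and Nanog-bearing embryos (horizontal axis) of the measured members of 9 gene lists (vertical axis). Each point is 1 gene and each bar is the median of its list, -2.46 for primitive endoderm, -0.19 for epiblast and 0.18 for trophectoderm.

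The epiblast and naive pluripotency list, with Nanog left out, had a median log2 fold change of -0.19 and a mean of -0.70 over 30 measured genes, 13 higher and 17 lower, and did not pass (adjusted p = 0.615). Its member Spp1, which encodes the secreted protein osteopontin, fell when adjusted over the list alone, by 3.37 (SE 0.67), at 46.4 ± 46.8 CPM in null (n = 4), 377 ± 124 in wild-type (n = 2) and 312 ± 1.81 in heterozygous embryos (n = 2). Fgf4, the growth factor gene of the epiblast, had 0, 0, 1 and 0 counts in the null embryos and 16, 1, 69 and 500 in the heterozygous female, heterozygous male, wild-type female and wild-type male. The trophectoderm list did not pass (25 measured genes, median 0.18 while the mean was -0.09, adjusted p = 0.699), with Eomes at 1.08 (SE 0.44) and Sfn at 0.60 (SE 0.23). Formative and primed epiblast genes gave an adjusted p of 0.802 (7 measured, median -0.34 while the mean was 0.17), with the DNA methyltransferase genes Dnmt3b at -0.69 (SE 0.30) and Dnmt3a at -0.54 (SE 0.36).

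None of the signalling lists passed in null embryos. The FGF and MAPK list had a median of -0.53 over 22 genes (adjusted p = 0.138), with Dusp6, a feedback phosphatase gene of the pathway, at -1.20 (SE 0.45). The BMP, Nodal and TGF-beta list had a median of -0.45 over 22 genes (adjusted p = 0.138), with the Nodal co-receptor gene Tdgf1 at -1.23 (SE 0.52) and Skil at 0.95 (SE 0.41). The Wnt list had a median of -0.65 over 22 genes (adjusted p = 0.315), with Apc at -1.05 (SE 0.56) and Gsk3b at 0.43 (SE 0.26). The LIF and STAT3 list had a median of -0.30 over 17 genes (adjusted p = 0.249), with Stat3 at -0.47 (SE 0.28) and the receptor subunit gene Il6st at -6.02 (SE 2.47), which had 8 counts in the null embryos together. The Hippo list (17 genes, median -0.01 while the mean was 0.19, adjusted p = 0.699) had Cyr61 at -1.77 (SE 0.81) and Wwtr1 at 0.94 (SE 0.55), and the Notch list (8 genes, median 0.19, adjusted p = 0.802) had Dll3 at 3.99 (SE 2.78) and Hes6 at -2.74 (SE 2.00).

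Lists of cell state gave no call. The p53 and apoptosis list had a median of 0.02 over 22 genes, with a mean just below 0 (adjusted p = 0.615), with the BH3-only gene Pmaip1 at -4.31 (SE 1.13) and the cell cycle inhibitor gene Cdkn1a at 1.36 (SE 0.40). Cell cycle genes had a median of -0.04 over 28 genes although the test leaned up (adjusted p = 0.615), with Mcm7 at -0.61 (SE 0.24) and Mki67 at -0.65 (SE 0.35). For glycolysis 17 of 21 genes were lower (median -0.16, adjusted p = 0.802), with Ldhb at 6.46 (SE 2.23) and Eno2 at -5.42 (SE 2.04). For chromatin regulators 21 of 29 genes were lower (median -0.32, adjusted p = 0.315), with Uhrf1 at -0.84 (SE 0.27) and Tet1 at -0.89 (SE 0.37), both genes of DNA methylation control. Immediate early and stress genes had a median of 0.17 and a mean of -0.18 over 19 genes (adjusted p = 0.615), with Fos at -4.98 (SE 2.48) and Hmox1 at 0.80 (SE 0.40). The fall of Fos rested on the heterozygous female, without which it was 0.94. Genes of the 2-cell stage (7 genes, median 0.05 while the mean was -0.04, adjusted p = 0.995) had Tdpoz1 at 3.64 (SE 1.67) and Eif1a at 0.31 (SE 0.21). Oocyte and maternal transcripts (10 genes, median -0.17 while the mean was 0.02, adjusted p = 0.699) included Npm2, with 0 counts in all null embryos, and Nlrp14, with 0 counts in all Nanog-bearing embryos.

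Markers of other cell types were examined as signs of foreign RNA. The blood cell list rose in null embryos (9 measured genes, median 4.69, 8 higher, adjusted p = 0.0322), with adjusted p = 0.471 with an estimated correlation. Its level was low everywhere, at a summed 12.0 ± 7.94 CPM in null (n = 4), 10.1 ± 2.89 in wild-type (n = 2) and 9.42 ± 13.2 in heterozygous embryos (n = 2), and the globin pairs Hba-a1 and Hba-a2, and Hbb-b1 and Hbb-b2, carried identical counts. Lyz2, a lysozyme gene, had 55 counts in the null embryos together and 0 in the Nanog-bearing embryos, and Laptm5 had 3 against 754, a ratio of 207 with a 95% counting interval from 70.7 to 1008. The blood call was kept in 1 of the 11 alternatives that left at least 5 genes, the one without the wild-type male (adjusted p = 0.0358). Among the others were the fits without the heterozygous female (0.386), without the heterozygous male (0.0758), without the wild-type female (0.207), without null F1 (0.267), without null M1 (0.0763) and without null M2 (0.0628). The fibroblast and mesenchymal list did not pass (12 genes, median 1.76, adjusted p = 0.520), with Fbln5 at 1 null count against 460 and Dcn at 109 against 0. Of the cumulus and oviduct list 2 genes were measured, too few to test, with Star at 1.02 (SE 1.75), or -0.96 without null F2, and Cyp11a1 (SE 5.91) with 0, 0, 69 and 0 counts in null embryos F1, F2, M1 and M2 and 370 of the 371 counts of the Nanog-bearing embryos in the wild-type female.

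Against wild-type embryos alone, the contrast that the series text names, Nanog fell by 8.00 (SE 0.53, adjusted p = 0.000490) and Nanogpd by 9.42 (SE 1.11, adjusted p = 0.0474). The next smallest adjusted p-values belonged to the peptide hormone gene Pyy, at -10.92 (SE 1.73, adjusted p = 0.347), to Aqp8, at -9.84 (SE 1.59, adjusted p = 0.347), and to Lamb1, at -2.79 (SE 0.49, adjusted p = 0.519). edgeR called 2 genes, with 500 at an unadjusted p under 0.05, against 94 calls by DESeq2 and 0 by limma voom with quality weights. Nanogpd lost its call without null F1 (adjusted p = 0.449), F2 (0.157), M2 (0.0667), the wild-type female (0.393) or the wild-type male (0.233), and Pyy gained one without the heterozygous female (0.0173), the heterozygous male (0.0208) or the wild-type male (0.0109). The size of the Pyy change depended on single embryos, from -13.37 without the wild-type male to -6.66 without the wild-type female, which held 7130 counts against 577 in the male.

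Against heterozygous embryos, which carry an intact Nanog allele, Nanog fell by 7.22 (SE 0.52, adjusted p = 0.00105). Nanogpd was at -8.68 (SE 1.09, adjusted p = 0.0847), Aqp8 at -8.72 (SE 1.54, adjusted p = 0.919), Spp1 at -3.19 (SE 0.72) and Lamb1 at -2.13 (SE 0.48). edgeR called 1 gene, with 357 at an unadjusted p under 0.05, against 80 calls by DESeq2 and 0 by limma voom with quality weights. Without null M1, Nanogpd was called as well (adjusted p = 0.0226).

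Heterozygous and wild-type embryos were compared to ask whether a missing allele alone changed expression. The genes with the smallest p-values were Kif3c, a kinesin gene, at 7.59 (SE 1.69), Oas1f at 8.90 (SE 2.16), Hmgn1, a nucleosome-binding protein gene, at -1.37 (SE 0.39), Pyy at -7.44 (SE 2.17, -10.90 to -3.84 with 1 embryo left out) and the lipid carrier gene Apoe at -2.87 (SE 0.85). edgeR called 0 genes, with 107 at an unadjusted p under 0.05, DESeq2 called 76 and limma voom with quality weights 0. With 2 embryos in each group the spread came from all 8 embryos.

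Between female and male embryos, Xist, the noncoding RNA that silences an X chromosome, was higher in females by 4.27 on the log2 scale (SE 0.44, adjusted p = 0.0283). Its antisense transcript Tsix was at 3.46 (SE 0.47, adjusted p = 0.153), a value that may hold Xist reads, since the 2 genes overlap and the use of strand in counting is not given. B230206F22Rik was at 6.94 (SE 1.01, adjusted p = 0.193), the Y-linked gene Eif2s3y at -8.37 (SE 1.53, adjusted p = 0.922) and its X-linked partner Eif2s3x at 1.05 (SE 0.22). edgeR called 1 gene, with 382 at an unadjusted p under 0.05, against 63 calls by DESeq2 and 2 by limma voom with quality weights. The Xist call was lost without the heterozygous female (adjusted p = 0.0537), the heterozygous male (0.0523), null F2 (0.360) or null M2 (0.126). The null library M1, labelled male, held 1.299 CPM of Y-linked transcripts against 131 to 276 CPM in the other 3 male embryos, and without it Eif2s3y was called too (adjusted p = 0.000595).

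Whether the effect of Nanog loss differed between the sexes was tested as an interaction. The genes with the smallest p-values were Spp1 at -3.23 (SE 0.51), Kirrel at -12.81 (SE 2.09), the growth factor gene Fgf10 at -8.06 (SE 1.59), Pcyt1b at 5.68 (SE 1.14) and Mfsd7c at 2.72 (SE 0.55), with female minus male as the direction. edgeR called 0 genes, with 513 at an unadjusted p under 0.05, DESeq2 called 102 and limma voom with quality weights 0. Without null M1, edgeR called 238 genes, 227 of them higher and 11 lower, in a fit where a single male null embryo was left and was assumed to vary like the other groups. In simulated data of this design, 0 of 66 genes with a 64-fold difference were recovered. The male null embryo left without M1 was M2, whose library had the most lost genes (809). The calls made without M1 therefore cannot be told apart from the losses of M2.

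The authors' deposited list of Nanog-regulated genes names 78 genes, 71 marked DOWN and 7 marked UP in null embryos, and how its genes were chosen is not stated. The list was deposited with these samples, so its direction was not taken as independent evidence. All 75 that could be tested here had the listed direction (71 lower and 4 higher), 1 was called over all genes tested (Nanog), 26 had an unadjusted p under 0.05, and 6 passed adjusted over the list alone, which was not taken as independent evidence either. The median log2 fold change of the 71 genes marked DOWN was -4.02. Of these 71, null F1 had 63 at 3 counts or fewer, F2 had 53, M2 had 58 and M1 had 20, against 1 to 3 in the Nanog-bearing embryos. Besides Nanog, the list holds Fgf4, Il6st and Pmaip1 among the genes marked DOWN and Ldhb among those marked UP. As given in the authors' deposited table in mm9, Fgf4 lies on chromosome 7 from 152047290 to 152051148, and Ldhb lies on chromosome 6 from 142438768 to 142456463.

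Lineage signatures taken from the cell lines asked whether genes typical of ES, TS or XEN cells moved in null embryos. The XEN signature had a median of -0.25 over 142 measured genes (83 lower, adjusted p = 0.0545), the ES signature -0.16 over 150 genes (84 lower, adjusted p = 0.132) and the TS signature -0.12 over 125 genes (67 lower, adjusted p = 0.789). With limma camera 0 of 3 signatures were called and 1 had an unadjusted p under 0.05. With fry both the ES and the XEN signature were called lower (adjusted p = 0.0108 each), a test that does not compare a signature with other genes. The ES signature holds Nanog and Nanogpd, its 2 members called lower over all genes tested, so part of its fall came from the targeted gene itself. The XEN median lay at percentile 8.16 of 10000 random gene sets, the ES median at 30.2 and the TS median at 64.3. The XEN signature was called without the heterozygous female (adjusted p = 0.0357), and both XEN and ES were called without null M2 (0.0491 each). Over all 16 alternatives the adjusted p of the XEN signature ranged from 0.0108 to 0.248.

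ES cells were compared with TS cells to describe the pluripotent against the trophoblast lineage. Pluripotency genes were higher in ES cells: Dppa5a by 9.21 on the log2 scale (SE 0.20, n = 2 ES and 3 TS lines), Pou5f1 by 8.30 (SE 0.26), Nanog by 8.75 (SE 0.45) and Gdf3 by 10.31 (SE 0.37). Trophoblast genes were lower in ES cells: the basic helix-loop-helix factor gene Hand1 at -10.54 (SE 0.65), the growth factor gene Igf2 at -10.55 (SE 0.85), the Wnt ligand gene Wnt7b at -9.86 (SE 0.28) and the FGF receptor gene Fgfr2 at -6.99 (SE 0.67). Sox2, used by both stem cell types, was 742 ± 56.6 CPM in ES (n = 4 libraries) and 205 ± 74.3 CPM in TS libraries (n = 6), a log2 difference of 1.80 (SE 0.31, adjusted p = 0.00435). Cdx2 was lower in ES cells, at -4.23 (SE 0.97, adjusted p = 0.0123), a call lost without ES line 2 (-3.52, adjusted p = 0.0721). Gata6 was at -2.83 (SE 0.36) and Gata4 at -1.90 (SE 0.24), both past the test.

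By list, 27 of 34 measured epiblast genes were higher in ES than in TS cells and 1 lower, 22 of 28 trophectoderm genes were lower and 2 higher, and 15 of 29 primitive endoderm genes were lower and 6 higher. The primitive endoderm genes went both ways, with Lama1 at 4.14 (SE 0.22) and Col4a1 at -5.78 (SE 0.34). In the signalling lists, Fgf4 was higher in ES cells by 10.33 (SE 0.55) and Phlda1 lower at -3.24 (SE 0.20), and the Wnt target gene Sp5 was higher by 8.57 (SE 0.44). Tdgf1 was higher by 9.54 (SE 0.46), and Klf4 and Lifr of the LIF list were higher by 6.07 (SE 0.26) and 3.67 (SE 0.27). The Hippo genes Cyr61 and Lats2 were at -4.43 (SE 0.34) and -1.97 (SE 0.24), and the Notch genes Dtx1, at 2.92 (SE 0.27), and Hes1 (SE 0.18) were higher in ES cells. edgeR called 6063 of 14687 tested genes, 2934 higher and 3129 lower in ES cells, and without ES line 1 or ES line 2 the count was 2429 or 2827. The largest increases by the fixed rule also included the zinc finger genes Zfp600 (7.72), Rex2 (7.72) and Zfp534 (6.36), and the largest decreases Rin3 (-8.59) and Tinagl1 (-7.72).

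**Figure D4:**
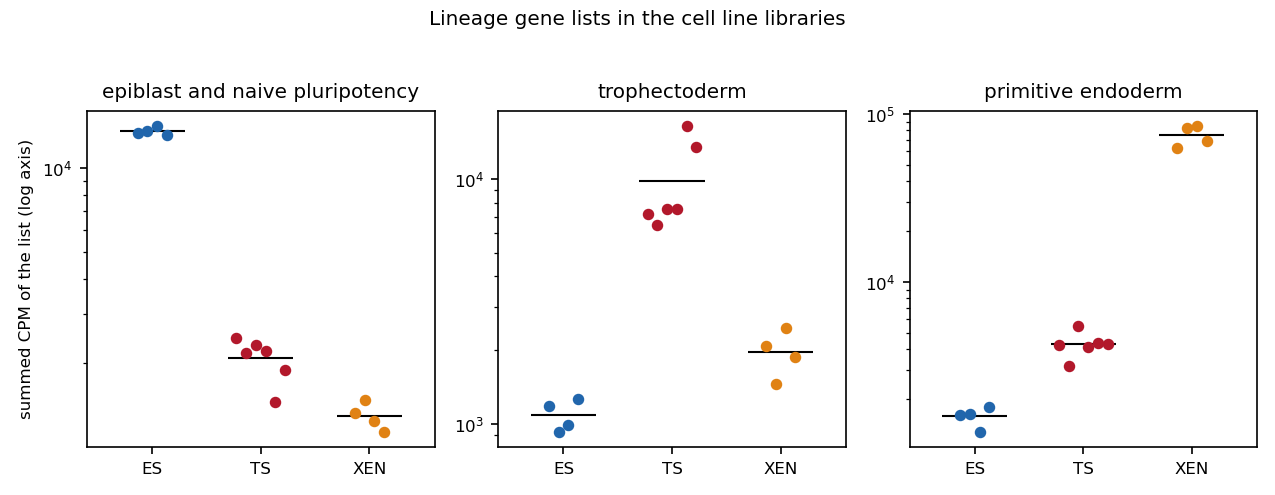
Summed CPM of 3 lineage gene lists (vertical log axes) in the 4 ES, 6 TS and 4 XEN libraries (horizontal axes). Each point is 1 library and each bar is the mean of its lineage, 13533 CPM of epiblast genes in ES, 9784 CPM of trophectoderm genes in TS and 74882 CPM of primitive endoderm genes in XEN libraries.

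ES cells were compared with XEN cells to describe the pluripotent against the primitive endoderm lineage. Pluripotency genes were higher in ES cells: Dppa5a by 11.51 (SE 0.26, n = 2 ES and 2 XEN lines), the orphan receptor genes Nr0b1 by 10.85 (SE 0.42) and Esrrb by 10.26 (SE 0.39), Nanog by 11.09 (SE 0.62), Sox2 by 10.25 (SE 0.53) and Pou5f1 by 8.61 (SE 0.32). Endoderm genes were lower in ES cells: the collagen IV genes Col4a1 at -10.36 (SE 0.41) and Col4a2 at -10.25 (SE 0.55), the endocytic adaptor gene Dab2 at -9.92 (SE 0.40), Gata6 at -9.83 (SE 0.42) and Gata4 at -7.90 (SE 0.33). Cdx2 did not pass, at 0.78 (SE 0.92, adjusted p = 0.519). It did without XEN line 2 (3.02, adjusted p = 0.0446) and with technical replicate 2 of each line alone (3.53, adjusted p = 0.00105). Its adjusted p ranged from 0.00105 to 0.949 over 16 alternatives. By list, 31 of 34 epiblast genes were higher and 1 lower, 27 of 29 primitive endoderm genes were lower and the other two did not pass, and trophectoderm genes were split, 6 of 28 higher and 7 lower. The remaining largest increases were Spp1 (11.96, SE 1.20), Laptm5 (10.68, SE 1.07) and the alkaline phosphatase gene Alpl (10.45, SE 0.43), and the remaining largest decreases were Pth1r (-10.01, SE 0.29) and the retinol carrier gene Rbp4 (-9.36, SE 0.54).

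Signalling genes differed between ES and XEN cells as well, with Fgf4 at 11.75 (SE 0.72) and Phlda1 at -4.77 (SE 0.22), Sp5 at 9.26 (SE 0.55) and Wnt7b at -7.62 (SE 0.26). The ligand genes Gdf3 and Bmp4 were higher in ES cells, by 10.38 (SE 0.44) and 9.42 (SE 0.43). Socs2 and Lif were at 5.70 (SE 0.42) and -2.61 (SE 0.31), the Hippo genes Cyr61 and Amotl2 at -5.87 (SE 0.38) and -2.15 (SE 0.21), and the Notch genes Rbpj and Notch4 at 2.06 (SE 0.18) and 6.66 (SE 0.58). edgeR called 6630 genes, 3431 higher and 3199 lower in ES cells, and 4071 or 3997 without ES line 1 or ES line 2. The share called higher depended on the scaling, 51.7% by TMM and 62.6% by upper quartile scaling (4216 higher and 2518 lower), which moved the median of all genes by 0.23 on the log2 scale.

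TS cells were compared with XEN cells to describe the 2 extraembryonic lineages against each other. Trophoblast genes were higher in TS cells: Hand1 by 11.30 (SE 0.67, n = 3 TS and 2 XEN lines), the transcription factor genes Tcfap2c by 11.09 (SE 0.51) and Elf5 by 9.82 (SE 0.37), the tight junction gene Cldn4 by 10.85 (SE 0.51) and Cdx2 by 5.01 (SE 1.01, adjusted p = 0.00769). Endoderm genes were lower in TS cells: Lama1 at -10.52 (SE 0.28), Sox17 at -11.17 (SE 0.35), Dab2 at -6.92 (SE 0.29), Gata6 at -7.00 (SE 0.30) and Gata4 at -6.00 (SE 0.25). Sox2 was higher in TS cells by 8.45 (SE 0.49) and Esrrb by 8.71 (SE 0.37), while Pou5f1 did not pass, at 0.31 (SE 0.22, adjusted p = 0.309). Nanog was higher by 2.35 (SE 0.52, adjusted p = 0.0111) at low levels in both, a call lost without XEN line 1 (adjusted p = 0.0624) or XEN line 2 (0.0616). By list, 20 of 28 trophectoderm genes were higher and 2 lower, 28 of 29 primitive endoderm genes were lower and the remaining gene did not pass, and 15 of 34 epiblast genes were higher and 6 lower. The remaining largest increases were Pramef12 (10.97, SE 0.66) and Sorl1 (10.58, SE 0.77), and the remaining largest decreases were Ctsh (-7.14, SE 0.63), Chst15 (-7.09, SE 0.43) and the activin antagonist gene Fst (-6.73, SE 0.71).

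In signalling, the receptor gene Fgfr1 and the cyclin gene Ccnd1 were higher in TS than in XEN cells, by 5.67 (SE 0.42) and 5.17 (SE 0.55), as were Wnt6 by 7.51 (SE 0.54) and Wnt7b by 2.23 (SE 0.18). Bmp4 and Smad7 were higher by 8.95 (SE 0.42) and 2.66 (SE 0.21), and Nrarp and Jag2 of the Notch list by 7.92 (SE 0.58) and 5.16 (SE 0.44). Lifr and Klf4 were lower in TS cells, at -5.40 (SE 0.29) and -4.30 (SE 0.25), as were the Hippo target genes Ankrd1 at -5.26 (SE 0.56) and Ctgf at -5.26 (SE 0.65). edgeR called 5385 genes, 2976 higher and 2409 lower in TS cells. The share called higher was 55.3% by TMM and 65.9% by upper quartile scaling (3494 higher and 1810 lower), which moved the median of all genes by 0.18. Both XEN lines were male, while the ES and TS lines were of both sexes, so sex was partly confounded with lineage. Only the ES libraries were titled serum free, so effects of the culture medium cannot be told apart from lineage in the ES comparisons. With sex as a covariate edgeR called 4212 genes for TS against XEN, 3908 of them shared with the 5385, and 5990 and 5705 for ES against TS and ES against XEN. The p-values of all line comparisons reflect the spread between lines, since the technical replicates were summed, and with 2 or 3 lines a lineage is described only by the lines at hand.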

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

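The tests of the share of the 10 highest genes, of the primitive endoderm genes and of the Y-linked transcripts of null M1 were chosen after the results they address had been seen, and the others beforehand.

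Among 76 groups of 4 or more values, 9 held a sample whose gap to the nearest of the others, relative to the range, exceeded Dixon's 95% limit, while chance gives about 1 in 20, or 3.8. In the Nanog-null embryos, Y-linked transcripts summed to 131 CPM in M2 against 1.299 to 3.52 in the other 3. Of those 3, F1 and F2 were labelled female, so the library at odds with its label was M1, labelled male, and not M2. Gata4 was 3.38 CPM in F2 against 0 to 0.104, and Nlrp14 was 11.9 CPM in F2 against 0 to 1.04. Null M1 stood apart in 3 genes: Pmaip1 at 6.19 CPM against 0.122 to 0.900, Ldhb at 2.60 CPM against 7.40 to 7.93, and Cyp11a1 at 3.59 CPM against 0 in the other 3. In the lines, where the 4 libraries of ES and of XEN cells come from 2 lines each, Gata4 was 2.93 CPM in replicate 2 of ES line 1 against 6.41 to 7.12. Gata6 was 467 CPM in replicate 2 of XEN line 1 against 250.0 to 254. Cdx2 was 7.89 CPM in replicate 1 of XEN line 2 against 0.338 to 1.00 in the other XEN libraries. No explanation was tested for the single genes.

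The counts of calls were compared with all 35 splits of the 8 embryos into 4 and 4, in a fit with 2 classes and no further term. For genotype 2 genes were called, and 3 of the 35 splits gave as many, the real one and the split by sex among them. The highest other split gave 4, so chance cannot be excluded for the count. That concerns the count and not Nanog itself, the targeted gene. For sex 3 genes were called in this fit, 2 of the 35 splits gave as many and the highest other gave 4, so chance cannot be excluded there either. For the gene lists 1 was called, 11 of the 35 splits gave as many and the highest other gave 3. For the lineage signatures 1 was called, 2 of the 35 splits gave as many and the highest other gave 2. Chance cannot be excluded for these counts.

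More genes at 3 counts or fewer, among those averaging at least 5 CPM in the other 7 embryos, were found in every Nanog-null library than in any Nanog-bearing one, while the number of genes detected overlapped between the groups (exact permutation p = 0.314). Library size is argued against as the cause: after thinning to equal totals, the lowest null library still had 66 more such genes than the highest Nanog-bearing one. A few genes taking most of the counts are argued against as well. The 10 highest genes held 9.59 ± 1.03% of the counts in null and 9.80 ± 0.816% in Nanog-bearing libraries (SD, n = 4 each). The measure chosen, the mean null share minus the highest Nanog-bearing share, was -1.38 percentage points. It decides little by itself, since a mean is set against a maximum. Random loss of transcripts in each library stays open as a candidate explanation. Pairs of null libraries shared 1.16 times the genes expected from independent loss (median of 6 pairs, 0.707 to 1.62), below the highest of 1000 simulations, 1.22, which is a lenient limit. Summed over these pairs, 350 genes were shared against 294 expected. The median was 10.3 in the 6 Nanog-bearing pairs, with 35 shared against 3.51 expected, and 1.40 in the 16 pairs with one of each. Why null libraries would lose more, through fewer cells, less RNA or the genotype itself, was not tested.

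Primitive endoderm genes were lower in null embryos. Random loss that hits genes independently in each library is argued against as the whole cause, since the list's median of -2.46 lay at percentile 0 of 10000 random lists matched on expression. Such draws cannot speak to loss that hits related genes together, and they are lenient. The chromatin list lay at percentile 0.01 without passing camera (adjusted p = 0.315). Because the list was picked for its small p, that p was set against the smallest of any tested list in each split: 1 of the 35 splits, the real one, gave as small a value (1.21e-06, smallest other 0.0178). This argues against chance for the value but cannot exclude it, since 1 is the smallest count that 35 splits allow. Of the 35 splits 5 called the list, the real one among them, and an estimated correlation gave 0.114 (range over 14 alternatives 9.62e-06 to 0.114). A lower share of inner cell mass cells cannot be told apart from a change in the primitive endoderm, because the list mean per embryo fell below that of the epiblast list by a difference of -1.41 (-2.19 against -0.78, exact permutation p = 0.0286), while the XEN and ES signatures fell alike, with changes of -0.99 and -1.01 (difference 0.022, exact permutation p = 0.771), and the TS signature changed by -0.63 (exact permutation p = 0.143). These signature means were not set against other genes, and the ES signature holds Nanog and Nanogpd. Among random sets the XEN median lay at percentile 8.16, the ES median at 30.2 and the TS median at 64.3, none of them outside the random range. The like fall of XEN and ES therefore does not by itself show a lower share of inner cell mass cells. The epiblast list, in contrast, lay below its random range, at percentile 1.55 (median -0.194, lower limit -0.172). Nor was the difference of -1.41 matched on expression, as the list means were 4.38 and 5.60 log2 CPM in Nanog-bearing embryos. A lower share thus stays open. Fewer primitive endoderm cells or lower expression in them were not tested.

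Null M1, labelled male, was without the Y-linked transcripts of the other male embryos. Random loss is argued against, since 0.0297% of the 3365 genes at or above 53.4 CPM in the other males, 1 gene, had 4 counts or fewer in this library. That level was the mean of 4 Y-linked genes in those males. Of these, Uty and Kdm5d, at most 27.8 and 7.92 CPM there, lay below it, and loss at their level was not measured. A normal XX female embryo under a male label is argued against by Xist at 44.2 CPM, below the female range of 280.3 to 892 and near the other males at 19.0 to 32.3. Loss of the Y chromosome or a female with a single X could give both values and was not tested. Without M1 the sex difference in the null effect rested on M2 as the only male null embryo. M2 was the library with the most lost genes (809), so a sex difference cannot be told apart from its losses.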

How the results depend on the processing

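Leaving out null embryos F1 and M2 together, and restricting lists to genes with a mean of at least 32 CPM, were alternatives chosen after the data were seen, and all others were planned. Where a left-out sample left 1 in a group, that sample was assumed to vary like the other groups. For null against Nanog-bearing embryos, 2 genes were called, and 1 with upper quartile scaling, the stricter filter, no robust shrinkage or without F1 and M2, 50 without a filter (29 higher and 21 lower), 87 with DESeq2 and 0 with limma voom. Leaving out 1 embryo gave 1 to 2. Against wild type, 2 were called, and 1 with the stricter filter, no robust shrinkage or without F1 and M2, 37 without a filter, 94 with DESeq2, 0 with limma voom and 1 to 3 with 1 embryo left out. Against heterozygous embryos, 1 was called, and 19 without a filter, 80 with DESeq2, 0 with limma voom, 2 with no sex term, 0 without F1 and M2 and 1 to 2 with 1 embryo left out. Between heterozygous and wild-type embryos the count was 4 without a filter, 76 with DESeq2 and 0 otherwise. Between the sexes it was 24 without a filter, 0 with the stricter filter, 63 with DESeq2, 2 with limma voom and 0 to 2 with 1 embryo left out. The interaction had 17 without a filter, 102 with DESeq2 and 0 to 238 with 1 embryo left out. The cause was not tested.

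In the lines, leaving out 1 line gave 2429 to 6233 genes for ES against TS, 3997 to 7646 for ES against XEN and 3808 to 5798 for TS against XEN, the lowest of the first 2 without an ES line, which leaves 1 ES line. With the replicate number as a block the counts were 8025, 8215 and 7275, against 8171, 8356 and 7469 for the same 14 libraries without the block, so the block had little effect. With sex as a covariate the counts were 5990, 5705 and 4212. Every line alternative but those with a line left out stayed within 1.5 times the count.

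For the gene lists, 2 were called, 0 with an estimated correlation, 1 with fry, DESeq2 size factors, wild type alone or without F1 and M2, and 1 to 2 with 1 embryo left out. The primitive endoderm list was called in 13 of 14 alternatives, and the blood list gave no value in 3 that left fewer than 5 of its genes. For the lineage signatures, 0 were called, 2 with fry, 1 with DESeq2 size factors, wild type alone, 100 genes or at least 32 CPM, and 0 to 2 with 1 embryo left out. The authors' list kept the listed direction for 75 of 75 genes against wild type alone.

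The following values reversed in direction, none of them past the test. For null against Nanog-bearing embryos with no sex term, Sox2 was 0.34 and Cyp11a1 0.91, and Cyp11a1 was 4.39 without F1 and M2. With 1 embryo left out, the range was -4.21 to 4.02 for Cyp11a1, -0.034 to 0.14 for Pou5f1, -5.78 to 0.94 for Fos, -0.96 to 2.02 for Star and -0.42 to 0.0064 for Cdx2. Pou5f1 in TS against XEN cells was -0.31 with technical replicate 1 alone. With 1 line left out, Cdx2 ranged from -0.66 to 3.02 in ES against XEN cells. Nlrp14 in TS against XEN cells did not change sign but was 0 without TS line 1 (range 0 to 3.89). The cause was not tested. Of the other values of named genes, 1087 in embryos and 4042 in lines kept direction and side of the threshold, 18 and 116 lost the call, and 55 and 2 gained it. For lists 244 values kept both, 11 lost the call and 1 gained it, and for signatures 39 kept both and 9 gained it. Depth limits the size of changes against groups at 0 counts, as for Srgn, at least 83.9-fold lower in null embryos.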

Other observations

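The values here were picked out after the data were seen, and the restriction to genes with a mean of at least 32 CPM was chosen after as well.

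Correlations of log expression between embryos were 0.857 to 0.882 among the 6 pairs of Nanog-bearing embryos and 0.749 to 0.806 among the 6 pairs of null embryos. In all, 25 genes were lost in 3 or more null and in no Nanog-bearing embryo, a number that 2 of the 35 splits reached (highest other 29). In all 4 null embryos 2 genes were lost, against 0.996 expected from independent loss, and of these Aqp8 was lost in no Nanog-bearing embryo.

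Genes of chromatin regulation were lower in null embryos for 21 of 29 members, and the median of -0.32 lay at percentile 0.01 of 10000 random lists matched on expression, while the list did not pass the camera test (adjusted p = 0.315, range over 14 alternatives 0.00542 to 0.890, called in 1, the one with genes of at least 32 CPM). Of the lists beyond the random range besides primitive endoderm, epiblast lay at percentile 1.55 and Wnt at 1.74, and on the high side fibroblast at 99.36 and blood at 99.98. In the lines, 12 of 29 chromatin genes were called higher in ES than in TS cells and 16 of 29 higher than in XEN cells, with Tet1 at 4.04 (SE 0.33) against TS cells.

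Of the 2-cell stage list 7 of 9 measured genes were called higher in ES than in TS cells, while the sum of the list was 294 CPM in ES and 284 CPM in TS libraries, with Zscan4f at 4.96 (SE 1.04) and 2.59 CPM in ES cells, a call lost without ES line 2 (4.20, adjusted p = 0.0730, range over 13 alternatives 0.000549 to 0.0730). Ooep of the oocyte list was higher by 10.53 (SE 0.45). The TS lines carried transcripts of the fibroblast list at 503 ± 353 CPM (SD, n = 6 libraries, 234 to 1194) against 608 in ES and 1538 in XEN libraries, with 13 of 22 genes called higher than in XEN cells. Against ES cells, where the sum was higher, 14 of the 22 genes were nonetheless called higher in TS cells and 1 lower (ES minus TS, median -3.84). Blood cell genes summed to 431 ± 313 CPM in TS and 544 in ES against 13.9 in XEN libraries. In that list Laptm5 was higher in TS than in XEN cells by 10.19 (SE 1.05), and Csf1r was lower in ES than in TS cells at -8.35 (SE 1.36).

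TS line 3, labelled male, held 22.2 and 26.3 CPM of Y-linked transcripts against 50.1 to 148 in the libraries of the other male lines, and its Xist was 68.7 and 42.9 CPM against 269 to 502 in the female TS libraries. The female ES line held 16.2 and 19.2 CPM of Xist.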
